A study of Mus musculus with 24 samples.

How the data were processed

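Total RNA of D3 embryonic stem cells with the scrambled sequence (siSCR) or the Prmt1 knockdown (siPRMT1) was measured on 24 Affymetrix whole-transcript arrays, 3 in each of 8 groups. Per the labels, RNA was purified on RNeasy columns, and 300 ng per sample were converted to biotinylated cDNA. The table deposited by the authors holds 1 expression value per probe set and array in log2 units, where the base was read from the range of the values, 2.14 to 14.5. How the authors summarised and normalized the probes is not given in the sources used here. The array medians ran from 7.47 to 7.67, no value was missing, and no 2 arrays were identical. Signals near background were not analysed apart, since no detection calls are given in the sources used here.

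The table has 35556 probe sets. A probe annotation listed 21789 of them with 1 gene symbol, 1621 with several and 12146 (34.2%) with none. Only sets with 1 symbol were tested, and for the 999 genes with over 1 set the set with the highest mean was kept, which left 19938 genes. Symbols were compared with the mouse gene table by gene identifier, where 21698 sets matched and 0 symbols needed an update. Probe sequences were not analysed here, so probes shared by members of gene families could not be told apart.

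Before the data were examined, the groups, 12 comparisons, their tests, the alternatives and 23 gene lists were fixed. Gene effects came from limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes), with 1 fit of 8 group means to all 24 arrays and 16 residual degrees of freedom. P-values were adjusted by the method of Benjamini and Hochberg over all genes of a comparison, and genes were called at an adjusted p under 0.05. No replicate block was used, because the labels do not say that equal replicate numbers in different groups belong together. Gene lists were tested with camera, with a preset correlation of 0.01 between genes and again with the correlation estimated, and p-values were adjusted over 276 tests of lists by comparisons. A list was called from the preset test, and the smallest list tested had to have 5 measured members. Of the 276 tests 82 were called with the preset and 35 with the estimated correlation. Counts adjusted over the list alone used the members of that list only. Prmt1 was also tested in each state with an exact permutation test. After the data were seen 3 comparisons were added: the average over undifferentiated and day 4 cells, vehicle against untreated in siPRMT1, and its difference from siSCR.

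The text names Prmt1 first. Per comparison it then names up to 10 of the largest rises and 10 of the largest falls among the called genes whose 3 arrays of one group all lay on the same side of the other group's 3. For the average the sign had to be the same in all 4 states, for interactions only the call counted, and for vehicle against untreated up to 5 genes each way were named. Symbols of predicted genes, RIKEN clones, microRNAs, small nucleolar RNA families, olfactory and vomeronasal receptors, immunoglobulin segments and major urinary proteins were passed over. Members of the fixed lists were named as members, and the members shown were chosen after their values were seen.

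Each comparison was repeated with a replicate block, with only the groups compared, after quantile normalization, after median centring, and without the dimmest 25% of genes. It was also repeated with the mean of a gene's probe sets, with a trend and robust variance, with array weights, with a 2-fold threshold, and without each array in turn. The 3 added comparisons were repeated in the same ways. Array scaling to one SD, the fit without the 6 siSCR arrays of DMSO and ATRA, and a covariate for fibroblast and feeder markers were added after the data were seen. The fit was tested on simulated data over 10 draws with 200 changed genes each. The noise had each gene's real residual spread, equal in all arrays and independent between genes. For a comparison of 3 against 3 arrays it recovered 82% of changes of 1.5-fold and 98.8% of 2-fold, and 6.8% of its calls were unchanged genes. For an interaction it recovered 58.2% and 90.6%, with 5.63% of calls on unchanged genes, and 0 calls had the wrong sign in either. A seeded list was called in 10 of 10 draws and 0 unchanged lists were.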

Results

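D3 cells are an established line of mouse embryonic stem cells. The arginine methyltransferase gene Prmt1 was knocked down in them (siPRMT1), and the controls received a scrambled sequence (siSCR). Both are called lines below, but whether the knockdown was stable or transient is not given in the sources used here. PRMT1 is the enzyme that places most asymmetric dimethylarginine in mammalian cells, on histone H4 among other proteins. RNA of both lines was hybridised to Affymetrix arrays in 4 states. These were undifferentiated cells, day 4 embryoid bodies (aggregates that differentiate once the cytokine LIF is withdrawn), embryoid bodies after 12 h with the vehicle DMSO, and embryoid bodies after 12 h with all-trans retinoic acid (ATRA, 5 micromol). Each of the 8 groups had 3 arrays, 24 in all, and the labels call them biological replicates. Below, a value after a gene is its log2 fold change ± standard error from the limma fit, with n = 3 arrays per group. A gene was called higher or lower when its adjusted p was under 0.05. The number of arrays limits the precision: the median standard error over 19938 genes was 0.0932. The fit takes 1 spread per gene for all 8 groups, although the groups scattered unequally. The lowest correlation between replicates was 0.982 in siSCR with ATRA and 0.995 in siPRMT1 with DMSO. Standard errors and adjusted p may therefore be too small where siSCR arrays of DMSO or ATRA are compared, and too large elsewhere.

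Prmt1 was lower in siPRMT1 in all 4 states. In undifferentiated cells its mean log2 value was 11.04 ± 0.08 (SD, n = 3) in siSCR and 9.67 ± 0.10 in siPRMT1, which left 38.6% of the control level (limma adjusted p = 1.26e-11). In day 4 embryoid bodies the means were 10.93 ± 0.085 and 10.3 ± 0.043, or 64.6% of control (adjusted p = 3.2e-07). With DMSO they were 11.53 ± 0.043 and 10.41 ± 0.037, or 46.2% (adjusted p = 2.48e-12). With ATRA they were 11.56 ± 0.022 and 10.12 ± 0.079, or 36.7% (adjusted p = 4.99e-14). In every state the 3 siPRMT1 arrays lay below the 3 siSCR arrays, and the two-sided exact permutation p was 0.1, the smallest that 3 against 3 can give. The knockdown was shallower at day 4 than in undifferentiated cells, by 0.74 ± 0.086 (adjusted p = 2.64e-06), and deeper with ATRA than with DMSO, by -0.33 ± 0.086 (adjusted p = 0.0396).

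**Figure D1:**
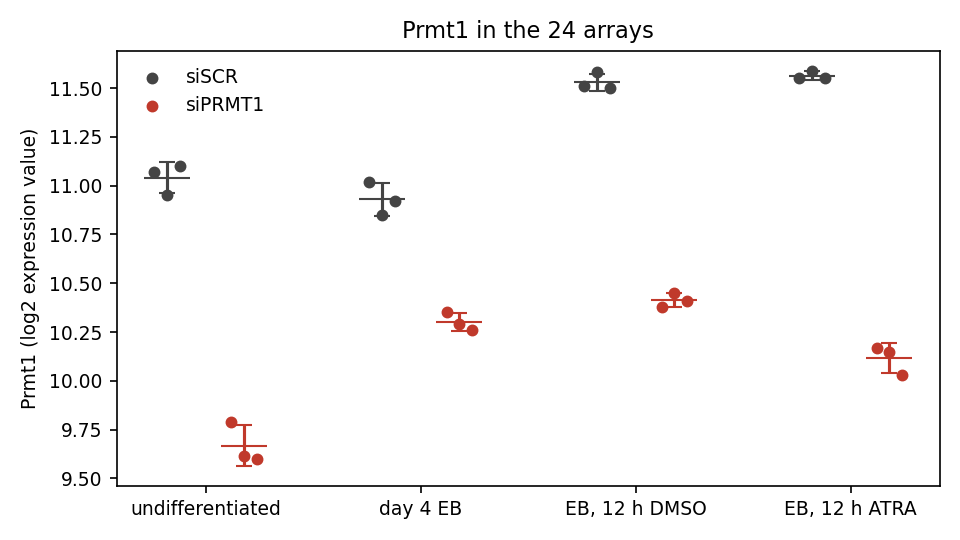
Prmt1 expression (log2, vertical axis) in each of the 24 arrays by state (horizontal axis), siSCR in dark grey and siPRMT1 in red. The horizontal line is the mean of 3 arrays and the bars are 1 SD. The siPRMT1 arrays lay below the siSCR arrays in every state, at 38.6%, 64.6%, 46.2% and 36.7% of the control mean.

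The arrays did not scatter evenly. The 6 siSCR arrays of DMSO and ATRA embryoid bodies stood apart from the other 18 on the leading principal component, which held 48.3% of the variance. Their scores ran from 76.9 to 90.3, against -39.9 to -14.3 for the other 18. The SD over genes within an array was 1.98 to 2.08 in the 6 and 2.15 to 2.27 in the 18. The correlation over genes of a member of the 6 with a member of the 18 was 0.946 to 0.966, while replicates of a group correlated at 0.982 to 0.998. The comparisons below that cross this border are the knockdown with DMSO or ATRA, the average over the 4 states, vehicle against untreated in siSCR, and the difference of that contrast between the lines. The ATRA interaction sets a response within the 6 against one within the 18. The labels give no batch, so the border cannot be told apart from the groups there. The ATRA response of each line, embryoid body formation, and the knockdown in undifferentiated and day 4 cells lie on one side of it.

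**Figure D2:**
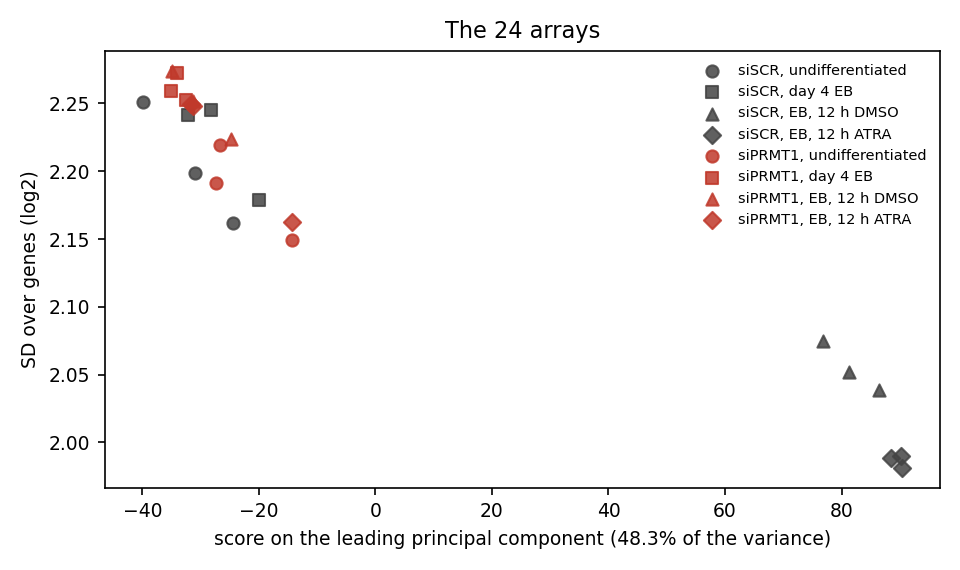
Each of the 24 arrays by its score on the leading principal component (horizontal axis, no unit) and the SD of its log2 values over genes (vertical axis). Colours give the line and symbols the state. The 6 siSCR arrays of DMSO and ATRA embryoid bodies sit at scores of 76.9 and above with an SD of at most 2.08, and the other 18 at -14.3 and below with an SD of at least 2.15.

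In undifferentiated cells, the question was which genes depend on Prmt1 before differentiation. Fosb and Fos, which encode subunits of the AP-1 transcription factor, were the genes raised most, by 2.56 ± 0.097 and 1.93 ± 0.11. Car4, a carbonic anhydrase, rose by 1.36 ± 0.12, the stress-induced factor Atf3 by 1.26 ± 0.077, the glycolytic enzyme Aldoc by 1.11 ± 0.058, and Mov10l1, a helicase of germline piRNA production, by 1.06 ± 0.077. The small RNA genes Rnu3a and Rny1 rose too (1.54 ± 0.11 and 1.14 ± 0.22), as did Cntd1 (1.34 ± 0.12) and the glycosyltransferase gene B4galnt2 (1.34 ± 0.14). The deepest falls were in Eif4a3l1 (-2.0 ± 0.23), the chemokine gene Ppbp (-1.80 ± 0.12) and genes known from the 2-cell-like state of embryonic stem cells, such as Zfp352 (-1.69 ± 0.090) and Usp17la (-1.48 ± 0.19). Pramel20 (-1.66), Pramel19 (-1.56), Tdpoz2 (-1.55), Tdpoz3 (-1.54), BC147527 (-1.54) and Arhgef26 (-1.43) fell too. Several of these belong to families of close copies, whose probes may be shared.

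In the same comparison, 22 measured genes of hypoxia and glycolysis moved mostly upward: 12 were higher, 1 lower and 9 not called (15 and 1 adjusted over the list alone). Ndrg1 rose by 0.93 ± 0.082, Bnip3 by 0.76 ± 0.062 and Pdk1 by 0.57 ± 0.046. The list had a median of 0.26, adjusted p = 9.1e-11, and adjusted p = 0.0402 with an estimated correlation. Of 15 sterol synthesis genes 9 rose and none fell (10 adjusted over the list alone), for example Insig1 (0.45 ± 0.066) and Srebf2 (0.37 ± 0.053). The sterol list had a median of 0.21, adjusted p = 4.83e-07, and adjusted p = 0.0233 with an estimated correlation. Targets of ATF4 and of the amino acid response were 12 higher, 0 lower and 8 not called of 20 measured (14 and 1 adjusted over the list alone). Atf3 led them, followed by Chac1 (0.58 ± 0.057), Aldh18a1 (0.39 ± 0.055) and Psat1 (0.36 ± 0.044). As a list they had a median of 0.18, adjusted p = 2.04e-07, and adjusted p = 0.0666 with an estimated correlation. The pluripotency list was 10 higher, 3 lower and 10 not called of 23 measured (12 and 4 adjusted over the list alone), with Klf2 (0.71 ± 0.067), Klf4 (0.55 ± 0.12) and Tcl1 (0.53 ± 0.081) higher and Tbx3 (-0.26 ± 0.064) lower. It had a median of 0.16, adjusted p = 0.00723, and adjusted p = 0.226 with an estimated correlation. Pou5f1, the gene of OCT4, was higher by 0.17 ± 0.041, and Nanog was not called (-0.064 ± 0.051). The endoderm list was 8 higher, 1 lower and 13 not called of 22 measured (8 and 1 adjusted over the list alone), led by Gata4 (0.46 ± 0.074). The endoderm list median was 0.13, adjusted p = 0.00293, and adjusted p = 0.396 with an estimated correlation.

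The largest group to fall in undifferentiated siPRMT1 cells was that of interferon-stimulated genes, 1 higher, 15 lower and 9 not called of 25 measured (2 and 15 adjusted over the list alone). Usp18 changed by -0.97 ± 0.11, Mx2 by -0.83 ± 0.17, Oas2 by -0.75 ± 0.12 and Ifit1 by -0.73 ± 0.18. Their median was -0.34, adjusted p = 1.61e-07, and adjusted p = 0.00318 with an estimated correlation. Fibroblast and feeder markers fell in the same arrays, 0 higher, 11 lower and 8 not called of 19 measured (0 and 11 adjusted over the list alone). The median was -0.28, adjusted p = 1.76e-06, and adjusted p = 0.025 with an estimated correlation. Examples are Prrx1 (-1.01 ± 0.13), S100a4 (-1.01 ± 0.11) and Acta2 (-0.96 ± 0.14). The labels say that the cells were passaged without feeders. Retinoic acid targets were 1 higher, 10 lower and 16 not called of 27 measured (1 and 12 adjusted over the list alone), among them Nr2f2 (-0.72 ± 0.088) and Nr2f1 (-0.71 ± 0.12). For the retinoic acid list the median was -0.18, adjusted p = 0.001, and adjusted p = 0.0628 with an estimated correlation. Cytosolic ribosomal protein genes were 3 higher, 0 lower and 13 not called of 16 measured (3 and 0 adjusted over the list alone). This median was 0.074, adjusted p = 0.00723, and adjusted p = 0.43 with an estimated correlation. The germline and 2-cell-like list went both ways, 4 higher, 6 lower and 8 not called of 18 measured (4 and 6 adjusted over the list alone). Usp17lc (-1.37 ± 0.13) and Tcstv3 (-1.18 ± 0.092) fell with Zfp352 and Usp17la, while the meiotic gene Sycp3 (0.90 ± 0.24) and the germ cell helicase gene Ddx4 (0.66 ± 0.14) rose, and the list as a whole was not called (adjusted p = 0.456).

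Over all 19938 genes, limma called 3747 between undifferentiated siPRMT1 and siSCR cells, 1522 higher and 2225 lower. At least 2-fold changes were few, 76 genes, 12 of them higher and 64 lower. With each array's mean over the fibroblast and feeder list as a covariate, 503 genes were called. The median standard error rose from 0.0932 to 0.228, and the fold changes moved too, correlating with those of the fit without it at r = 0.616 across genes.

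At day 4 of embryoid body culture the knockdown comparison asked whether early differentiation depends on Prmt1. Cer1, a secreted antagonist of Nodal and BMP, was higher by 1.88 ± 0.18 and the Wnt transcription factor Lef1 by 1.71 ± 0.059. Apoa1 was higher by 1.70 ± 0.082 and the retinoic acid hydroxylase gene Cyp26a1 by 1.61 ± 0.098. Spink1 (2.13 ± 0.14), the cadherin gene Cdh9 (1.85 ± 0.15), Pilra (1.84 ± 0.15), the retinoid X receptor gene Rxrg (1.76 ± 0.083), Ugt2b34 (1.74 ± 0.098) and Vat1l (1.56 ± 0.12) complete the 10 largest rises. Lower were the transglutaminase gene Tgm2 (-1.51 ± 0.076), the hypoxia-inducible genes Ndufa4l2 (-1.31 ± 0.10) and Bhlhe40 (-1.24 ± 0.10), and Prdm1 (-1.28 ± 0.089), the repressor that specifies primordial germ cells. Crtac1, Ccng2, Scarna17, Got1l1, Fxyd6 and Wfdc2 were lower by between 1.08 and 1.20.

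The endoderm list showed the most uniform shift at day 4, 19 higher, 0 lower and 3 not called of 22 measured (20 and 0 adjusted over the list alone). Transthyretin (Ttr, 1.33 ± 0.12), Apob (1.13 ± 0.11) and the pioneer factor gene Foxa2 (0.94 ± 0.059) followed Apoa1, and Gata4 (0.76 ± 0.074) and Gata6 (0.75 ± 0.055) were higher as well. The list had a median of 0.68, adjusted p = 3.21e-21, and adjusted p = 0.00243 with an estimated correlation. Primed epiblast genes were 10 higher, 1 lower and 4 not called of 15 measured (10 and 1 adjusted over the list alone). Beside Cer1 and Lef1 they included Fgf5 (1.37 ± 0.11), Grhl2 (1.28 ± 0.096) and the DNA methyltransferase genes Dnmt3a (1.11 ± 0.060) and Dnmt3b (0.90 ± 0.059), while Lefty2 was lower (-0.30 ± 0.087). The epiblast list had a median of 0.87, adjusted p = 3.21e-11, and adjusted p = 0.000305 with an estimated correlation. Pluripotency genes were 3 higher, 10 lower and 10 not called of 23 measured (3 and 12 adjusted over the list alone). Tcl1 (-0.79 ± 0.081), Klf2 (-0.42 ± 0.067), Tfcp2l1 (-0.41 ± 0.043) and Nanog (-0.25 ± 0.051) were lower. The pluripotency list had a median of -0.17, adjusted p = 0.000595, and adjusted p = 0.0961 with an estimated correlation. Retinoic acid targets were 7 higher, 1 lower and 19 not called of 27 measured (7 and 1 adjusted over the list alone). Wt1 (1.14 ± 0.089) and Rarb (0.53 ± 0.079) rose with Cyp26a1, and Tgm2 fell. The list median was 0.038, adjusted p = 0.0348, and adjusted p = 0.282 with an estimated correlation.

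**Figure D3:**
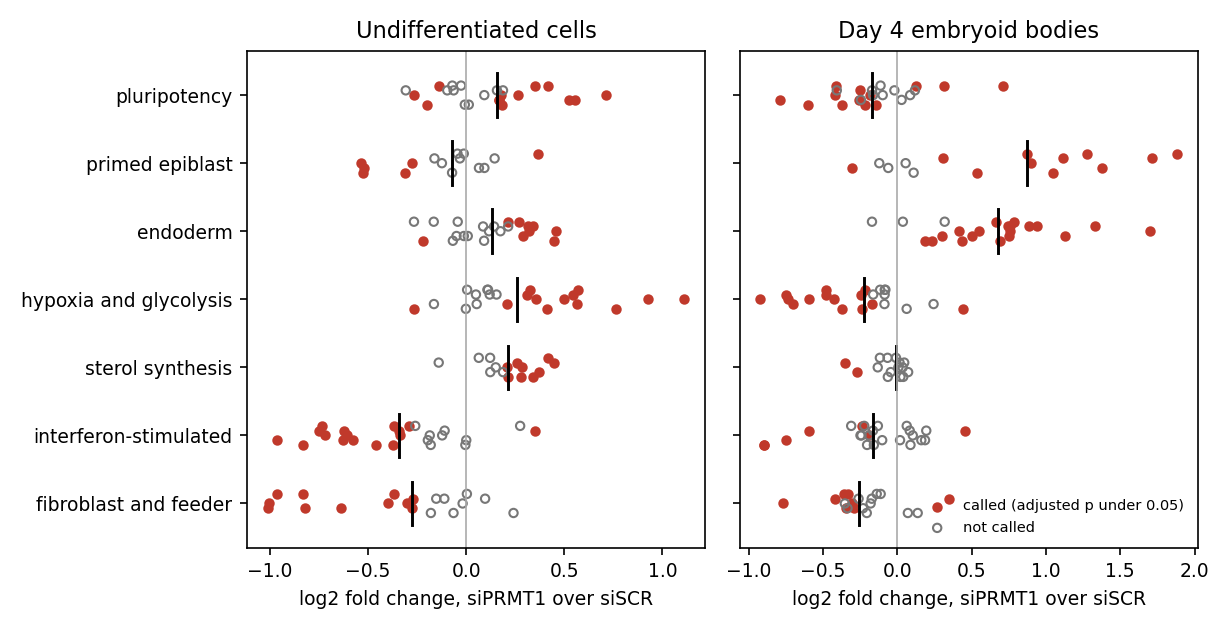
Log2 fold change of siPRMT1 over siSCR (horizontal axes) for each measured member of 7 gene lists, in undifferentiated cells (left) and day 4 embryoid bodies (right). Red points were called and open points were not, and the vertical bar is the list's median. The endoderm median lay at 0.13 in undifferentiated cells and at 0.68 at day 4, and that of hypoxia and glycolysis at 0.26 and -0.23.

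Hypoxia and glycolysis genes were lower in siPRMT1 at day 4, 1 higher, 13 lower and 8 not called of 22 measured (2 and 15 adjusted over the list alone). Aldoc (-0.92 ± 0.058), Vegfa (-0.75 ± 0.063), Egln3 (-0.74 ± 0.059) and Ndrg1 (-0.59 ± 0.082) fell. The list's median was -0.23, adjusted p = 9.18e-10, and adjusted p = 0.0509 with an estimated correlation. Interferon-stimulated genes were 1 higher, 6 lower and 18 not called of 25 measured (1 and 7 adjusted over the list alone), for example Xaf1 (-0.90 ± 0.094) and Ifitm3 (-0.89 ± 0.051). The interferon list median was -0.16, adjusted p = 0.00589, and adjusted p = 0.09 with an estimated correlation. Fibroblast and feeder markers moved with them, 1 higher, 7 lower and 11 not called of 19 measured (1 and 11 adjusted over the list alone), for example Dcn (-0.77 ± 0.079) and Timp1 (-0.42 ± 0.064). Their median was -0.26, adjusted p = 9.23e-05, and adjusted p = 0.0595 with an estimated correlation. In all, limma called 3669 genes at day 4, 2272 higher and 1397 lower, and 92 changed at least 2-fold. The share called higher was 61.9%, but it was 82.9% with arrays centred on their medians and 51.9% with arrays scaled to one SD, so the balance of directions rested on the scaling. With the feeder list's mean as a covariate 1025 genes were called, with a median standard error of 0.155 and fold changes that correlated with the former at r = 0.687 across genes.

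The knockdown effects in undifferentiated and day 4 cells were not alike. Across all genes, which are not independent replicates, they correlated at r = -0.182 (rho = -0.217, jackknife SE over the 12 arrays 0.09), and the correlation stayed between -0.223 and -0.119 with any one array left out. Of the genes called in both states, 981 went in opposite directions, 208 were higher in both and 201 lower in both, against 173.4 and 155.9 for independent lists. Among the opposite ones were Aldoc, Ndrg1, Bnip3, Klf2, Tcl1, Tgm2 (0.62 ± 0.076 in undifferentiated cells) and Rarb (-0.40 ± 0.079). The average over these states, added after the data were seen, called 2797 genes, 1486 higher and 1311 lower, and the share called higher was 53.1% as fitted and 68.2% with centring. It was led by Car4 (1.08 ± 0.085), Pilra (0.95 ± 0.11), Lef1 (0.93 ± 0.042) and Apoa1 (0.91 ± 0.058) above and, after Prmt1 (-1.0 ± 0.043), by the kallikrein gene Klk10 (-0.97 ± 0.050), Ppbp (-0.91 ± 0.089) and Crygd (-0.85 ± 0.096) below.

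With DMSO or ATRA, the knockdown comparison set arrays on both sides of the border described above against each other. Apoa1 was higher in siPRMT1 by 2.66 ± 0.082 with ATRA, Cer1 by 3.21 ± 0.18 and Spink1 by 2.84 ± 0.14 with DMSO, and Csn3, the gene of kappa-casein, by 2.66 ± 0.13 with ATRA. Among the largest differences, however, were genes not raised most at day 4: Terc, the RNA component of telomerase, at 3.91 ± 0.12 and 3.56 ± 0.12, Uqcc2 at 3.04 ± 0.10 and 3.03 ± 0.10, Pbx3 at 2.69 ± 0.097 and 2.60 ± 0.097, and Reep6 at 2.57 ± 0.074 and 2.51 ± 0.074. Others higher were Map7d3 (2.69 ± 0.10), Cdh9 (2.62 ± 0.15), Gkn2 (2.61 ± 0.13) and Rxrg (2.60 ± 0.083) with DMSO, and Ly96 (2.93 ± 0.23), Selenop (2.62 ± 0.10), Smim8 (2.54 ± 0.13) and Fam171b (2.49 ± 0.12) with ATRA. Usp17ld was far lower (-5.34 ± 0.17 and -4.92 ± 0.17), as were AY036118 (-2.68 ± 0.18 and -2.89 ± 0.18), Micos10 (-2.61 ± 0.079 and -2.66 ± 0.079) and Rida (-2.31 ± 0.089 and -2.19 ± 0.089). Clp1, Zswim7 and Gemin6 were lower in both, Pcgf1, Anxa1 and Meiob were named with DMSO, and Pmaip1, Cetn4 and Pmvk with ATRA.

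Endoderm genes were higher in siPRMT1 with DMSO, 18 higher, 1 lower and 3 not called of 22 measured (18 and 1 adjusted over the list alone). With ATRA they were 18 higher, 0 lower and 4 not called of 22 measured (18 and 1 adjusted over the list alone). With DMSO the list had a median of 0.74, adjusted p = 5.71e-07, and adjusted p = 0.09 with an estimated correlation. With ATRA it had a median of 0.82, adjusted p = 9.03e-07, and adjusted p = 0.0957 with an estimated correlation. Gata6 (1.63 ± 0.055 and 1.58 ± 0.055), Apob (1.52 ± 0.11 and 1.42 ± 0.11) and Sox7 (1.35 ± 0.11 and 1.42 ± 0.11) were among them. Genes of the primed epiblast were 11 higher, 1 lower and 3 not called of 15 measured (11 and 1 adjusted over the list alone) with DMSO, led by Cer1, Lef1 (2.38 ± 0.059) and Zic2 (2.37 ± 0.096). The median was 0.93, adjusted p = 0.000181, and adjusted p = 0.0146 with an estimated correlation. Hypoxia and glycolysis genes were 1 higher, 10 lower and 11 not called of 22 measured (1 and 10 adjusted over the list alone) with DMSO, for example Hk2 (-1.32 ± 0.057). For the hypoxia list the median was -0.20, adjusted p = 0.0113, and adjusted p = 0.524 with an estimated correlation. Retinoic acid targets were 18 higher, 4 lower and 5 not called of 27 measured (18 and 4 adjusted over the list alone) with ATRA, for example Hoxb2 (2.35 ± 0.12), Meis2 (2.25 ± 0.080) and Rarb (1.75 ± 0.079). This median was 0.63, adjusted p = 0.000181, and adjusted p = 0.0405 with an estimated correlation. Hox paralogues 1 to 5 were 9 higher, 3 lower and 2 not called of 14 measured (9 and 3 adjusted over the list alone) with ATRA. The Hox list had a median of 0.74, adjusted p = 0.0442, and adjusted p = 0.278 with an estimated correlation. Imprinted genes were 13 higher, 5 lower and 3 not called of 21 measured (13 and 6 adjusted over the list alone) with ATRA, among them Peg10 (1.63 ± 0.065) and Igf2 (1.56 ± 0.082). The imprinted list had a median of 0.55, adjusted p = 0.0445, and adjusted p = 0.336 with an estimated correlation. Ribosomal protein genes were 1 higher, 9 lower and 6 not called of 16 measured (1 and 8 adjusted over the list alone). As a list they had a median of -0.15, adjusted p = 0.0445, and adjusted p = 0.6 with an estimated correlation. Cell cycle genes such as E2f1 (1.14 ± 0.068 and 1.18 ± 0.068) were 15 higher, 5 lower and 5 not called of 25 measured (15 and 6 adjusted over the list alone) with DMSO. With ATRA they were 16 higher, 5 lower and 4 not called of 25 measured (16 and 5 adjusted over the list alone). Their medians of 0.36 (adjusted p = 0.0192, and adjusted p = 0.43 with an estimated correlation) and 0.37 (adjusted p = 0.00804, and adjusted p = 0.35 with an estimated correlation) turned to -0.073 and -0.15 with arrays scaled to one SD.

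With DMSO limma called 13135 genes, 6234 higher and 6901 lower, and with ATRA 13984, 6414 higher and 7570 lower. At least 2-fold changes numbered 1467 and 1606. The shares called higher, 47.5% and 45.9%, were 59.7% and 59.8% with arrays centred on their medians and 58.3% and 58.1% without the dimmest 25% of genes, and 51.8% and 52.7% after quantile normalization. With ATRA, centring moved the median of all genes from -0.106 to 0.026. Both effects correlated with that at day 4, with r = 0.394 for DMSO and r = 0.341 for ATRA across genes, and with each other at r = 0.927.

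Averaged over the 4 states, Apoa1 (1.74 ± 0.041), Gkn2 (1.57 ± 0.065), Meioc (1.49 ± 0.074) and Car4 (1.46 ± 0.060) were raised most. Pbx3, Pilra, Pcbd1, Pla2g12b, Mvb12b and Mogat2 rose by between 1.24 and 1.41. After Prmt1 (-1.14 ± 0.031), Prl2c5 (-1.08 ± 0.084), Fmr1nb (-1.03 ± 0.044), Sohlh2 (-0.95 ± 0.029), Tfrc (-0.88 ± 0.027) and Pmaip1 (-0.88 ± 0.029) were lowered most. Ankrd37, Ly75, Antkmt and Slc13a5 followed. Endoderm genes were 20 higher, 2 lower and 0 not called of 22 measured (20 and 2 adjusted over the list alone). The endoderm list median was 0.56, adjusted p = 2.63e-09, and adjusted p = 0.0441 with an estimated correlation. Primed epiblast genes were 11 higher, 2 lower and 2 not called of 15 measured (11 and 2 adjusted over the list alone). Their median was 0.49, adjusted p = 0.00082, and adjusted p = 0.0234 with an estimated correlation. Retinoic acid targets were 16 higher, 5 lower and 6 not called of 27 measured (16 and 5 adjusted over the list alone). The median was 0.23, adjusted p = 0.015, and adjusted p = 0.19 with an estimated correlation. Interferon-stimulated genes were 3 higher, 14 lower and 8 not called of 25 measured (3 and 14 adjusted over the list alone). The interferon list had a median of -0.20, adjusted p = 0.0203, and adjusted p = 0.174 with an estimated correlation. Fibroblast and feeder markers were 1 higher, 14 lower and 4 not called of 19 measured (1 and 14 adjusted over the list alone). For the feeder list the median was -0.26, adjusted p = 0.00318, and adjusted p = 0.177 with an estimated correlation. Hox paralogues 6 to 13, for example Hoxc8 (-0.50 ± 0.082), were 0 higher, 13 lower and 10 not called of 23 measured (0 and 13 adjusted over the list alone). This median was -0.16, adjusted p = 0.0288, and adjusted p = 0.571 with an estimated correlation. Cell cycle genes were 17 higher, 4 lower and 4 not called of 25 measured (17 and 4 adjusted over the list alone). They had a median of 0.19, adjusted p = 0.00394, and adjusted p = 0.305 with an estimated correlation, but their median was -0.040 with arrays scaled to one SD. The average called 14209 genes, 6381 higher and 7828 lower, 121 of them at least 2-fold. Over undifferentiated and day 4 cells alone it called 2797, and 4050 without the 6 arrays in the fit. Over all arrays the share called higher was 44.9% as fitted, 62.3% with centring, 51.6% after quantile normalization and 56.2% without the dimmest genes.

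Embryoid body formation compared day 4 aggregates with undifferentiated cells of the same line. In siSCR the genes raised most included the endocytic receptor gene Lrp2 (3.46 ± 0.084), the thyroid hormone carrier gene Ttr (3.19 ± 0.12) and the cathepsin gene Ctsh (3.04 ± 0.12). Otx2 rose by 2.93 ± 0.12, and Lgals2 (3.42 ± 0.097), Gkn2 (3.24 ± 0.13), Pga5 (3.22 ± 0.076), Pla2g7, Clic6 and Enpp3 rose too. The deepest falls were in the matrix gene Efemp1 (-3.61 ± 0.11), Usp17la (-3.53 ± 0.19), Tdpoz3 (-3.52 ± 0.16), Eif4a3l1 (-3.38 ± 0.23), the interferon-inducible Trim30a (-3.33 ± 0.13), the chemokine gene Ccl3 (-3.32 ± 0.10) and Usp18 (-3.27 ± 0.11), with Medag, Tmem92 and Obox6. In siPRMT1 Ttr (4.31 ± 0.12), Lrp2 (4.18 ± 0.084), Pga5 (4.05 ± 0.076), Spink1 (3.65 ± 0.14) and Otx2 (3.44 ± 0.12) led, followed by Gkn2, Clic6, Cdh9, Has2 and Muc13. Fos (-4.38 ± 0.11) and Fosb (-3.46 ± 0.097) fell most there, with Medag, Efemp1, Tgm2 (-2.63 ± 0.076), the cyclooxygenase gene Ptgs2 (-2.47 ± 0.060), Trim30a, Vcam1, Egr1 (-2.42 ± 0.092) and Usp18.

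Endoderm genes rose during aggregation in siSCR, 18 higher, 2 lower and 2 not called of 22 measured (20 and 2 adjusted over the list alone). They rose in siPRMT1, 20 higher, 0 lower and 2 not called of 22 measured (20 and 1 adjusted over the list alone). In siSCR they had a median of 0.65, adjusted p = 5.8e-16, and adjusted p = 0.00737 with an estimated correlation. In siPRMT1 they had a median of 1.20, adjusted p = 4.29e-18, and adjusted p = 0.00427 with an estimated correlation. Cubn (2.35 ± 0.095 and 2.58 ± 0.095) and Apob (1.30 ± 0.11 and 2.44 ± 0.11) are examples. Genes of the primed epiblast were 10 higher, 1 lower and 4 not called of 15 measured (12 and 1 adjusted over the list alone) in siSCR. The list's median was 0.40, adjusted p = 4.49e-07, and adjusted p = 0.00182 with an estimated correlation. The siPRMT1 counts were 13 higher, 1 lower and 1 not called of 15 measured (13 and 1 adjusted over the list alone). The epiblast list median was 1.55, adjusted p = 4.21e-12, and adjusted p = 0.000281 with an estimated correlation. Fgf5 rose by 1.29 ± 0.11 and 2.60 ± 0.11, and Lef1 by 1.30 ± 0.059 and 2.87 ± 0.059. Pluripotency genes rose slightly as a list in siSCR, with 10 higher, 3 lower and 10 not called of 23 measured (10 and 4 adjusted over the list alone), where Fgf4 (0.73 ± 0.077) rose and Fbxo15 (-0.92 ± 0.064) fell. The pluripotency list had a median of 0.094, adjusted p = 0.0442, and adjusted p = 0.402 with an estimated correlation. Germline and 2-cell-like genes were 1 higher, 10 lower and 7 not called of 18 measured (1 and 10 adjusted over the list alone) in siSCR. Their median was -0.41, adjusted p = 3.7e-06, and adjusted p = 0.0509 with an estimated correlation. In siPRMT1 these were 1 higher, 9 lower and 8 not called of 18 measured (1 and 10 adjusted over the list alone). The median was -0.33, adjusted p = 0.00106, and adjusted p = 0.187 with an estimated correlation. Zfp352 changed by -2.98 ± 0.090 and -1.26 ± 0.090, while Prdm1 rose by 2.24 ± 0.089 and 0.59 ± 0.089. Imprinted genes were 11 higher, 4 lower and 6 not called of 21 measured (11 and 5 adjusted over the list alone) in siSCR, among them Peg3 (1.04 ± 0.096) and Igf2 (0.96 ± 0.082). As a list they had a median of 0.22, adjusted p = 0.0292, and adjusted p = 0.299 with an estimated correlation.

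Hypoxia and glycolysis genes rose in siSCR, 19 higher, 0 lower and 3 not called of 22 measured (20 and 0 adjusted over the list alone), with Ndrg1 at 1.90 ± 0.082 and Egln3 at 1.89 ± 0.059. The hypoxia list median was 0.36, adjusted p = 3.84e-13, and adjusted p = 0.0223 with an estimated correlation. In siPRMT1 they were 5 higher, 7 lower and 10 not called of 22 measured (5 and 7 adjusted over the list alone) and not called as a list (adjusted p = 0.42). ATF4 and amino acid response genes, such as the cystine transporter gene Slc7a11 (1.93 ± 0.15 and 2.18 ± 0.15), were 16 higher, 0 lower and 4 not called of 20 measured (18 and 0 adjusted over the list alone) in siSCR. For the ATF4 list the median was 0.40, adjusted p = 1.71e-11, and adjusted p = 0.0223 with an estimated correlation. The siPRMT1 counts were 10 higher, 2 lower and 8 not called of 20 measured (10 and 2 adjusted over the list alone). This median was 0.19, adjusted p = 0.0171, and adjusted p = 0.511 with an estimated correlation. Sterol synthesis genes were 12 higher, 0 lower and 3 not called of 15 measured (13 and 0 adjusted over the list alone) in siSCR, for example Lss (0.61 ± 0.069). Their median was 0.31, adjusted p = 6.92e-07, and adjusted p = 0.0242 with an estimated correlation. Retinoic acid targets fell in siSCR, 4 higher, 16 lower and 7 not called of 27 measured (4 and 16 adjusted over the list alone), with Stra8 at -2.44 ± 0.14. The median was -0.37, adjusted p = 7.28e-05, and adjusted p = 0.0293 with an estimated correlation. Hox paralogues 1 to 5 were 0 higher, 9 lower and 5 not called of 14 measured (0 and 9 adjusted over the list alone) in siSCR, for example Hoxa5 (-1.48 ± 0.11). The Hox list had a median of -0.36, adjusted p = 5.96e-05, and adjusted p = 0.0229 with an estimated correlation. In siPRMT1 these were 0 higher, 10 lower and 4 not called of 14 measured (0 and 11 adjusted over the list alone). The list's median was -0.36, adjusted p = 0.00106, and adjusted p = 0.0533 with an estimated correlation. Ribosomal protein genes were 0 higher, 8 lower and 8 not called of 16 measured (0 and 8 adjusted over the list alone) in siPRMT1. They had a median of -0.11, adjusted p = 0.0196, and adjusted p = 0.511 with an estimated correlation, and their median was 0.0029 with arrays centred on their medians.

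Interferon-stimulated genes fell in both lines on aggregation, 1 higher, 19 lower and 5 not called of 25 measured (1 and 19 adjusted over the list alone) in siSCR. In siPRMT1 they were 1 higher, 18 lower and 6 not called of 25 measured (1 and 18 adjusted over the list alone). Mx2 changed by -2.63 ± 0.17 and -1.96 ± 0.17, and Ifit3 by -2.34 ± 0.11 and -1.92 ± 0.11. The siSCR test had a median of -0.66, adjusted p = 2.26e-12, and adjusted p = 0.00032 with an estimated correlation. The siPRMT1 test had a median of -0.61, adjusted p = 7.28e-08, and adjusted p = 0.00278 with an estimated correlation. Fibroblast and feeder markers fell in the same arrays, 0 higher, 15 lower and 4 not called of 19 measured (0 and 16 adjusted over the list alone) in siSCR. In siPRMT1 the markers were 0 higher, 16 lower and 3 not called of 19 measured (0 and 16 adjusted over the list alone). Lox changed by -2.07 ± 0.14 and -1.76 ± 0.14 and Thy1 by -1.84 ± 0.069 and -1.34 ± 0.069. Markers in siSCR had a median of -1.0, adjusted p = 1.15e-15, and adjusted p = 0.000769 with an estimated correlation. Those in siPRMT1 had a median of -0.87, adjusted p = 4.5e-11, and adjusted p = 0.00318 with an estimated correlation.

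In numbers, limma called 5632 genes in siSCR (2891 higher, 2741 lower, 550 at least 2-fold) and 8252 in siPRMT1 (4582 higher, 3670 lower, 653 at least 2-fold). Called in both lines were 3820 genes, of which 1764 rose in both and 1493 fell in both, against 664.4 and 504.5 for independent lists, and 563 went opposite ways. With the feeder list's mean as a covariate 24 and 54 genes were called. The median standard error rose to 0.6 and 0.517, and the fold changes were not kept, with r = 0.297 and r = 0.268 across genes to those without the covariate. The share called higher in siPRMT1 was 55.5% as fitted, 75.0% with arrays centred on their medians and 48.9% with arrays scaled to one SD.

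The interaction tested whether aggregation changed genes differently in siPRMT1. The log2 change was more positive in siPRMT1 for Spink1 (2.35 ± 0.20), Arhgef26 (2.32 ± 0.17), Eif4a3l1 (2.29 ± 0.33), the lysophosphatidic acid receptor gene Lpar4 (2.14 ± 0.17), Rxrg (2.12 ± 0.12), the interferon-inducible GTPase gene Irgm1 (2.07 ± 0.20), the cytokine gene Il33 (2.00 ± 0.21), Sema6a, Ly96 and Cer1 (1.89 ± 0.26). Fosb (-2.60 ± 0.14), Fos (-2.44 ± 0.16), Ndufa4l2 (-2.29 ± 0.15), Tgm2 (-2.13 ± 0.11), Aldoc (-2.03 ± 0.082), the protease inhibitor gene A2m (-1.99 ± 0.12), Cntd1, Crtac1, Got1l1 and Rnu3a differed the other way. Primed epiblast genes were 11 higher, 0 lower and 4 not called of 15 measured (11 and 0 adjusted over the list alone), Dnmt3a (1.27 ± 0.085) and Fst (1.36 ± 0.091) among them. As a list they had a median of 1.06, adjusted p = 2.87e-10, and adjusted p = 0.00032 with an estimated correlation. Endoderm genes were 14 higher, 1 lower and 7 not called of 22 measured (16 and 1 adjusted over the list alone). For the endoderm list the median was 0.44, adjusted p = 1.33e-08, and adjusted p = 0.0532 with an estimated correlation. Retinoic acid targets were 12 higher, 1 lower and 14 not called of 27 measured (12 and 1 adjusted over the list alone), led by Cyp26a1 (1.82 ± 0.14). This median was 0.33, adjusted p = 0.000226, and adjusted p = 0.0431 with an estimated correlation. Hypoxia and glycolysis genes were 1 higher, 18 lower and 3 not called of 22 measured (1 and 19 adjusted over the list alone), for example Ndrg1 (-1.52 ± 0.12) and Vegfa (-1.06 ± 0.088). The hypoxia list had a median of -0.47, adjusted p = 8.27e-15, and adjusted p = 0.0146 with an estimated correlation.

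In the same interaction, pluripotency genes were 3 higher, 11 lower and 9 not called of 23 measured (4 and 13 adjusted over the list alone), for example Klf2 (-1.13 ± 0.095). As a list they had a median of -0.28, adjusted p = 9.79e-05, and adjusted p = 0.0595 with an estimated correlation. ATF4 and amino acid response genes were 0 higher, 9 lower and 11 not called of 20 measured (0 and 10 adjusted over the list alone), for example Ddit4 (-0.99 ± 0.089). The ATF4 list median was -0.20, adjusted p = 1.92e-05, and adjusted p = 0.154 with an estimated correlation. Sterol synthesis genes were 0 higher, 8 lower and 7 not called of 15 measured (0 and 9 adjusted over the list alone), for example Srebf2 (-0.64 ± 0.075). The sterol test had a median of -0.25, adjusted p = 3.27e-05, and adjusted p = 0.0532 with an estimated correlation. Ribosomal protein genes were 0 higher, 4 lower and 12 not called of 16 measured (0 and 4 adjusted over the list alone). Their median was -0.10, adjusted p = 0.0171, and adjusted p = 0.509 with an estimated correlation. Limma called 4754 genes, 2994 with a more positive and 1760 with a more negative log2 change in siPRMT1, and 343 differed at least 2-fold. The share more positive was 63%, 78% with centring and 52.7% with one SD, so the balance again rested on the scaling.

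Retinoic acid binds nuclear receptors that switch on genes of posterior identity and of its own turnover, and 12 h of ATRA was compared with DMSO in each line. In siSCR the response was led by Stra8 (4.07 ± 0.14), the retinoic acid-induced gene of meiotic entry, the water channel gene Aqp3 (2.94 ± 0.078), the retinal reductase gene Dhrs3 (2.39 ± 0.062), Hoxa5 (2.21 ± 0.11) and Cyp26a1 (1.91 ± 0.098). Acp5 (1.60 ± 0.055), Dusp9 (1.54 ± 0.067), Gca, Ankrd44 and Actn3 rose by less. Otx2 changed by -2.20 ± 0.12, and Zfp459 (-1.41 ± 0.12), Platr8 (-1.36 ± 0.13), the fatty acid transporter gene Slc27a2 (-1.33 ± 0.087), Casq2, Lrrc34, Slc6a15, Dnmt3l (-1.17 ± 0.062), Ddx58 and Socs2 fell as well. In siPRMT1 Stra8 (4.19 ± 0.14), Csn3 (3.28 ± 0.13), Hoxa5 (3.14 ± 0.11), Hoxb2 (2.96 ± 0.12), Hoxb5 (2.79 ± 0.11), Aqp3 (2.67 ± 0.078), Dhrs3 (2.61 ± 0.062), Hoxb1 (2.50 ± 0.078), the receptor gene Rarb (2.35 ± 0.079) and the retinol transporter gene Stra6 (2.35 ± 0.072) rose most. Otx2 (-2.69 ± 0.12), Cer1 (-2.64 ± 0.18), Lef1 (-2.60 ± 0.059), Platr8 (-2.09 ± 0.13), Foxd3 (-1.79 ± 0.11), Slc27a2, Cdh9, Lhx1 (-1.63 ± 0.099), Fgf5 (-1.60 ± 0.11) and Pilra fell most.

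Retinoic acid targets rose in siSCR, 17 higher, 2 lower and 8 not called of 27 measured (17 and 2 adjusted over the list alone). Their median was 0.38, adjusted p = 4.15e-10, and adjusted p = 0.00182 with an estimated correlation. The siPRMT1 counts were 19 higher, 1 lower and 7 not called of 27 measured (19 and 1 adjusted over the list alone). The median was 0.97, adjusted p = 1.44e-26, and adjusted p = 4.36e-05 with an estimated correlation. Beyond the genes above, Nrip1 rose by 1.18 ± 0.062 and 1.37 ± 0.062 and Crabp2 by 0.97 ± 0.083 and 1.79 ± 0.083. Hox paralogues 1 to 5 were 12 higher, 0 lower and 2 not called of 14 measured (12 and 0 adjusted over the list alone) in siSCR. The Hox list median was 0.56, adjusted p = 3.15e-09, and adjusted p = 0.00182 with an estimated correlation. In siPRMT1 these were 11 higher, 0 lower and 3 not called of 14 measured (11 and 0 adjusted over the list alone). Their median was 1.44, adjusted p = 2.97e-22, and adjusted p = 4.36e-05 with an estimated correlation. Hoxa2, Hoxb1 and Hoxb2 belong to both of these lists. Hox paralogues 6 to 13 were 5 higher, 0 lower and 18 not called of 23 measured (5 and 0 adjusted over the list alone) in siSCR. The median was 0.16, adjusted p = 0.0122, and adjusted p = 0.502 with an estimated correlation. In siPRMT1 they were 6 higher, 0 lower and 17 not called of 23 measured (6 and 0 adjusted over the list alone). For the Hox list the median was 0.16, adjusted p = 0.00103, and adjusted p = 0.325 with an estimated correlation. Hoxb13 was the member raised most in both (0.62 ± 0.085 and 0.67 ± 0.085).

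Pluripotency genes fell with ATRA in siSCR, 1 higher, 10 lower and 12 not called of 23 measured (1 and 11 adjusted over the list alone). For the pluripotency list the median was -0.15, adjusted p = 0.000131, and adjusted p = 0.0632 with an estimated correlation. The siPRMT1 counts were 1 higher, 11 lower and 11 not called of 23 measured (1 and 13 adjusted over the list alone). This median was -0.17, adjusted p = 1e-07, and adjusted p = 0.0146 with an estimated correlation. Zfp42, the gene of REX1, changed by -0.52 ± 0.054 and -0.58 ± 0.054, and Tbx3 rose by 0.40 ± 0.064 and 0.65 ± 0.064. Endoderm genes were 2 higher, 11 lower and 9 not called of 22 measured (2 and 12 adjusted over the list alone) in siSCR. This median was -0.23, adjusted p = 0.00106, and adjusted p = 0.33 with an estimated correlation. In siPRMT1 these were 2 higher, 6 lower and 14 not called of 22 measured (2 and 11 adjusted over the list alone). The endoderm list had a median of -0.18, adjusted p = 0.000106, and adjusted p = 0.226 with an estimated correlation. Hnf4a changed by -0.53 ± 0.067 and -0.58 ± 0.067, and Gata6 rose by 0.50 ± 0.055 and 0.45 ± 0.055. Primed epiblast genes fell in siPRMT1, 1 higher, 10 lower and 4 not called of 15 measured (1 and 10 adjusted over the list alone). The median was -0.37, adjusted p = 6.04e-11, and adjusted p = 0.000305 with an estimated correlation. Arginine methyltransferase genes and their partners were 1 higher, 8 lower and 6 not called of 15 measured (2 and 8 adjusted over the list alone) in siSCR. The list's median was -0.13, adjusted p = 0.0155, and adjusted p = 0.396 with an estimated correlation. In siPRMT1 they were 2 higher, 3 lower and 10 not called of 15 measured (2 and 3 adjusted over the list alone). The methyltransferase list median was -0.094, adjusted p = 0.0166, and adjusted p = 0.397 with an estimated correlation. Hypoxia and glycolysis genes were 2 higher, 6 lower and 14 not called of 22 measured (2 and 6 adjusted over the list alone) in siSCR, for example Adm (-0.73 ± 0.12). For the hypoxia list the median was -0.087, adjusted p = 0.00318, and adjusted p = 0.437 with an estimated correlation. In siPRMT1 the ATF4 list was 7 higher, 0 lower and 13 not called of 20 measured (10 and 0 adjusted over the list alone). This list had a median of 0.14, adjusted p = 0.00369, and adjusted p = 0.396 with an estimated correlation. The ribosomal protein list was 0 higher, 1 lower and 15 not called of 16 measured (0 and 1 adjusted over the list alone). This median was -0.10, adjusted p = 0.00168, and adjusted p = 0.328 with an estimated correlation.

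**Figure D4:**
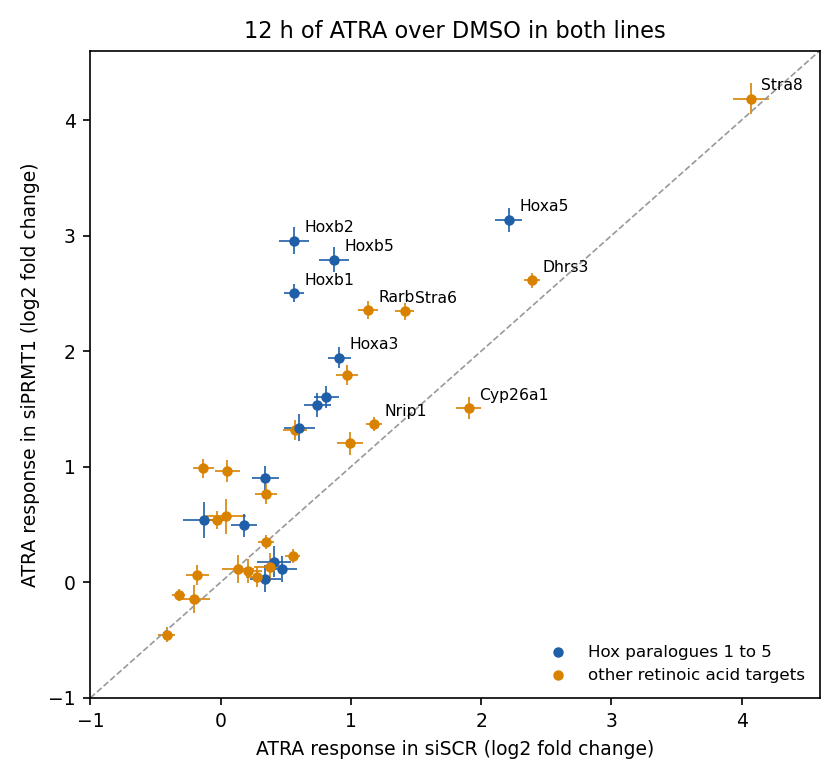
Log2 fold change of 12 h of ATRA over DMSO in siSCR (horizontal axis) and in siPRMT1 (vertical axis) for retinoic acid targets (orange) and Hox paralogues 1 to 5 (blue), with bars of 1 SE and a dashed line where both are equal. Stra8 lay near that line at 4.07 and 4.19, and Hoxb2 above it at 0.56 and 2.96.

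Limma called 4663 genes with ATRA in siSCR, 2229 higher and 2434 lower, 63 of them at least 2-fold, and 2391 in siPRMT1, 1207 higher and 1184 lower, 138 of them at least 2-fold. The order of the lines was not settled, as the counts were 544 and 2995 with only the groups compared in the fit and 1567 and 7640 with array weights. The share called higher in siSCR was 47.8% as fitted, 32.8% with arrays centred on their medians and 52.2% after quantile normalization. Called in both lines were 1350 genes, of which 641 rose in both, 673 fell in both and 36 went opposite ways, against 135 and 145 expected for independent lists in the same directions. Over the 5704 genes called in either line, the siPRMT1 response was 0.984 times that in siSCR (slope, jackknife SE 0.095), so no difference in its general size was resolved.

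Single genes did differ between the lines in their response to ATRA. The rise was larger in siPRMT1 for Csn3 (2.51 ± 0.19), Hoxb2 (2.40 ± 0.16), Hoxb1 (1.94 ± 0.11), Hoxb5 (1.92 ± 0.16) and Rarb (1.22 ± 0.11), and the interaction was also positive for Pgam2 (1.69 ± 0.13), the ephrin receptor gene Epha7 (1.49 ± 0.16), Gabrg1, Pmp22 and Chrna5. It was negative for Cer1 (-2.64 ± 0.26), Lef1 (-2.09 ± 0.083), Pilra (-1.61 ± 0.22), the kinase gene Pim2 (-1.55 ± 0.11), Cdh9, Serpina1c, Fgf5 (-1.33 ± 0.15), Foxd3 (-1.33 ± 0.15), Fgf15 and Lhx1 (-1.27 ± 0.14). Hox paralogues 1 to 5 were 9 higher, 0 lower and 5 not called of 14 measured (11 and 1 adjusted over the list alone), and Hoxa3 (1.03 ± 0.13) was one of them. Their test had a median of 0.76, adjusted p = 2.37e-13, and adjusted p = 0.00032 with an estimated correlation. Retinoic acid targets were 10 higher, 1 lower and 16 not called of 27 measured (14 and 2 adjusted over the list alone), with Meis2 (1.12 ± 0.11), Stra6 (0.93 ± 0.10) and Crabp2 (0.82 ± 0.12) among those higher. The retinoic acid list had a median of 0.22, adjusted p = 7.29e-11, and adjusted p = 0.00142 with an estimated correlation. Stra8 (0.12 ± 0.19), Dhrs3 (0.22 ± 0.088) and Cyp26a1 (-0.40 ± 0.14) were not called. Genes of the primed epiblast were 1 higher, 7 lower and 7 not called of 15 measured (1 and 9 adjusted over the list alone), and Grhl2 (-1.13 ± 0.14) fell further in siPRMT1 beside Cer1, Lef1 and Fgf5. As a list they had a median of -0.46, adjusted p = 7.67e-11, and adjusted p = 0.000305 with an estimated correlation. The levels with DMSO were higher in siPRMT1 than in siSCR, for example Cer1 at 10.03 against 6.82 and Lef1 at 10.32 against 7.93. With ATRA the lines were closer, at 7.39 against 6.81 and 7.71 against 7.42. At day 4, on one side of the border, they stood at 8.7 against 6.82 and 9.88 against 8.17. A lower start of siSCR, seen without the border too, cannot be told apart from a weaker response. Ribosomal protein genes were 0 higher, 1 lower and 15 not called of 16 measured (0 and 1 adjusted over the list alone). The ribosomal list median was -0.083, adjusted p = 0.00572, and adjusted p = 0.406 with an estimated correlation.

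Limma called 646 genes in this interaction, 382 positive and 264 negative, 31 of them at least 2-fold. Of the called genes that rose in both lines, 59 rose more and 8 less in siPRMT1, and of those that fell in both, 23 fell more and 16 less. The count was 135 with only the groups compared in the fit and 405 with centred arrays. It also hung on single siPRMT1 arrays, with 382, 313 and 401 genes without DMSO replicate 1, 2 or 3 and 311, 304 and 897 without ATRA replicate 1, 2 or 3.

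Vehicle-treated embryoid bodies were also compared with untreated ones. On which day the 12 h fell is not clear from the labels, so the groups may differ in culture time as well as in DMSO. In siSCR, where it crosses the border between the 6 arrays and the other 18, Usp17ld (5.26 ± 0.17), Micos10 (2.68 ± 0.079), AY036118 (2.54 ± 0.18), Pcgf1 (2.40 ± 0.12) and Rida (2.35 ± 0.089) were higher with DMSO, and Terc (-4.37 ± 0.12), Uqcc2 (-3.04 ± 0.10), Smim8 (-2.54 ± 0.13), Pbx3 (-2.52 ± 0.097) and DQ267102 (-2.50 ± 0.091) were lower. Limma called 12189 genes there, 6147 higher and 6042 lower, 1202 of them at least 2-fold, and the share called higher was 50.4% as fitted and 40.0% without the dimmest 25% of genes. Imprinted genes were 2 higher, 14 lower and 5 not called of 21 measured (3 and 14 adjusted over the list alone), for example Phlda2 (-1.67 ± 0.089). Their median was -0.28, adjusted p = 0.0379, and adjusted p = 0.324 with an estimated correlation. In siPRMT1, a comparison added after the data were seen, 92 genes were called, 61 higher and 31 lower. This count was not stable, with 286 genes without the 6 arrays in the fit and 2536 with array weights. It was 35, 36 and 34 without siPRMT1 day 4 replicate 1, 2 or 3, and 32, 30 and 29 without DMSO replicate 1, 2 or 3. The share called higher was 66.3% as fitted, 87.2% with centring, 83.3% with one SD, 51.0% without the 6 arrays in the fit and 31.6% with array weights. The retinol-binding protein gene Rbp4 (1.44 ± 0.12), Cer1 (1.33 ± 0.18), Ier3 (0.94 ± 0.15), alpha-fetoprotein (Afp, 0.88 ± 0.15) and Adm (0.80 ± 0.12) rose most, and Banp (-0.62 ± 0.070), Pla2g4c (-0.49 ± 0.11), Cyp11a1 (-0.43 ± 0.092), Msc and Ppp1r10 fell most. Endoderm genes were 5 higher, 0 lower and 17 not called of 22 measured (7 and 0 adjusted over the list alone) there. Their test had a median of 0.15, adjusted p = 2.63e-14, and adjusted p = 0.0105 with an estimated correlation. Primed epiblast genes were 2 higher, 0 lower and 13 not called of 15 measured (7 and 1 adjusted over the list alone). The median was 0.17, adjusted p = 6e-08, and adjusted p = 0.00156 with an estimated correlation.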

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

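The tests below that used vehicle against untreated in siPRMT1, the scaling of the 6 arrays, the targets outside the Hox list, the lists called on aggregation and the scaling of the primed epiblast list were chosen after the result was seen. Groups of 3 arrays were not tested for single arrays far from the rest. What brought the values here was a tested difference between the lines in the same contrast, or a signal in probe sets that the comparisons leave out.

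The response to aggregation differed between the lines in 4754 genes and the response to ATRA in 646, by the interaction tests of limma. The response to vehicle culture differed in 8889. On aggregation the difference was positive for Spink1 (2.35), Arhgef26 (2.32), Eif4a3l1 (2.29), Lpar4 (2.14), Rxrg (2.12), Irgm1 (2.07), Il33 (2.00), Sema6a (1.97), Ly96 (1.93) and Cer1 (1.89). It was negative for Fosb (-2.60), Fos (-2.44), Ndufa4l2 (-2.29), Tgm2 (-2.13), Aldoc (-2.03), A2m (-1.99), Cntd1 (-1.95), Crtac1 (-1.86), Got1l1 (-1.83) and Rnu3a (-1.73). The list medians of this difference were 1.06 for primed epiblast, 0.33 for retinoic acid targets and -0.47 for hypoxia and glycolysis.

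With ATRA the difference between the lines was positive for Csn3 (2.51), Hoxb2 (2.40), Hoxb1 (1.94), Hoxb5 (1.92), Pgam2 (1.69), Epha7 (1.49), Gabrg1 (1.28), Rarb (1.22), Pmp22 (1.19) and Chrna5 (1.13). It was negative for Cer1 (-2.64), Lef1 (-2.09), Pilra (-1.61), Pim2 (-1.55), Cdh9 (-1.38), Serpina1c (-1.37), Fgf5 (-1.33), Foxd3 (-1.33), Fgf15 (-1.30) and Lhx1 (-1.27). The list medians were -0.46 for primed epiblast, 0.22 for retinoic acid targets and 0.76 for Hox paralogues 1 to 5. Among the 12146 probe sets with no listed gene, limma called 528 for the knockdown in undifferentiated cells, 351 for the knockdown at day 4 and 103 for ATRA in siPRMT1.

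The 6 siSCR arrays of DMSO and ATRA embryoid bodies stood apart from the other 18. A response to vehicle culture common to both lines is unlikely to be the whole cause, since in siPRMT1 the same contrast called 92 genes (286 without the 6 arrays in the fit and 2536 with array weights), against 12189 in siSCR. Between-array scaling cannot be the whole cause, as the siSCR count was still 11074 at the lowest of 3 scalings. Separate handling of these arrays would also shift probe sets with no listed gene. Of these 46.8% were called (61.1% of genes), against at most 13.6% in comparisons within one side of the border, as this explanation needs. A vehicle response of siSCR alone was not tested and remains open, as line and set cannot be separated.

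Hox paralogues 1 to 5 except Hoxd1, Hoxd3 and Hoxd4 rose more with ATRA in siPRMT1 than in siSCR. The list's median difference was 0.763 (bootstrap interval over genes, taken as independent, 0.312 to 1.03, 11 of 14 larger). With every array scaled to one SD the median was still 0.689, so the narrower SD of the siSCR arrays accounts for little of it. This scaling could not have removed the difference, because the SDs lie close together: 1.98 to 2.08 in the 6 arrays and 2.15 to 2.27 in the other 18. A raised floor of dim genes stays open: 104 other genes as dim that rose had a median difference of 0.313 (0.221 to 0.403), with 86 larger in siPRMT1. A shorter or weaker exposure of the siSCR cultures stays open as well, as the 18 retinoic acid targets outside the Hox list that rose in either line had a median difference of 0.32 (0.0562 to 0.748), with 13 larger, and all 24 measured outside it, not chosen for rising, had 0.212 (-0.0028 to 0.528), with 16 larger. An effect of Prmt1 on Hox genes is the biological reading, and no test here separates it from those 2.

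Endoderm and primed epiblast genes were higher in siPRMT1 at day 4. The same course of differentiation, only further along, stays open, because 1 stage after aggregation cannot show which lists turn back later: of 12 lists called on aggregation in siSCR, the knockdown at day 4 moved 4 in the same direction, 3 in the opposite one, and 5 were not called (4, 2 and 3 of the 9 called on aggregation with an estimated correlation). The hypoxia and glycolysis list, which rose on aggregation in siSCR (median 0.359), was one of the 3, with a median knockdown difference of -0.226 at day 4: adjusted p = 9.18e-10 was past the bound first set against this explanation, but it was 0.0509 with an estimated correlation, and asking for both was decided after these values were seen. Between-array scaling is unlikely, since the endoderm median of 0.676 was 0.614 at the lowest of 3 scalings, and the primed epiblast median of 0.873 was 0.801. An effect of Prmt1 on these lineages remains possible, and with 1 knockdown line and 1 control line a difference between lines of other origin was not tested.

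The array labels were also exchanged within the comparisons. For the 3 against 3 comparisons 10 splits are too few for a share under 0.05, and the real split was the highest, 1 of 10, in each. The highest other split called 0 genes for the knockdown in undifferentiated cells (real 3747), at day 4 (3669), with DMSO (13135) and with ATRA (13984). It also called 0 for embryoid body formation in siPRMT1 (8252), ATRA in siPRMT1 (2391) and vehicle against untreated in siSCR (12189) and siPRMT1 (92). It called 1 gene for embryoid body formation in siSCR (5632) and 304 for ATRA in siSCR (4663). Chance labels, with no line difference in any state, can be excluded for the average over 4 states (14209, highest other 3943), its version over undifferentiated and day 4 cells (2797, highest other 1549) and the aggregation interaction (4754, highest other 2243), each 1 of 100. With DMSO and ATRA the line labels coincide with the border, so the average over 4 states cannot be told apart from it. For the aggregation interaction the exchange removes every line difference, so the count does not test the interaction alone. Chance labels cannot be excluded by this count for the ATRA interaction, where 11 of 100 splits called as many as the real 646 and the highest called 3292. All 10 others were among the 11 splits in which the number of arrays exchanged per treatment differed by at least 2 between the lines. In those the contrast adds parts of the ATRA responses of both lines instead of subtracting them, so this count cannot decide on the interaction. The other 88 called at most 498. For the vehicle interaction 8 of 100 splits called as many as the real 8889, with 10169 at the highest. All 7 others were among the 11 splits that left the siSCR labels whole or reversed them, which called at least 8503, and the other 88 called at most 12, so this count follows the siSCR arrays.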

How the results depend on the processing

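The limits are 3 arrays per group, the 6 siSCR arrays that stood apart, and a median standard error of 0.0932, which rose to 0.132 for interactions. Dim signals near background could not be separated from absent ones. Of 7976 alternatives of 439 log2 fold changes of named genes, 7798 stayed on their side of the test's threshold, 172 lost the call and 2 gained it. Of the 172, 92 were with the feeder covariate and 52 with 1 array left out. With the feeder covariate 4 changed sign: Sycp3 for the knockdown in undifferentiated cells (-0.42), Apob on aggregation in siSCR (-0.14), and Meg3 (0.079) and Prdm1 (-0.062) on aggregation in siPRMT1. Array scaling to one SD, the feeder covariate, the fits without the 6 arrays and every alternative of the 3 added comparisons were chosen after seeing the data. For the shifts below the cause was not tested.

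With array weights limma called 7218 genes for the knockdown in undifferentiated cells, 6106 at day 4, 8969 for embryoid body formation in siSCR, 7688 for its interaction, 1567 for ATRA in siSCR and 7640 for ATRA in siPRMT1. It called 2536 for vehicle against untreated in siPRMT1 and 5487 for the average over undifferentiated and day 4 cells. With only the groups compared it called 544 for ATRA in siSCR and 135 for the ATRA interaction. Median centring gave 405 for the latter and 47 for vehicle against untreated in siPRMT1, where one SD gave 60 and the variance with trend 145. The feeder covariate left 503 and 1025 genes for the knockdown in undifferentiated and day 4 cells, and 24 and 54 for embryoid body formation in siSCR and siPRMT1. Without the 6 arrays in the fit the average over the remaining states called 4050, and vehicle against untreated in siPRMT1 286. Asking for at least 2-fold left 76, 92, 1467 and 1606 genes for the knockdown in the 4 states in order, and 121 for their average. It left 550, 653 and 343 for embryoid body formation in siSCR, siPRMT1 and their difference. It left 63, 138 and 31 for ATRA in the same order, and 1202 for vehicle against untreated in siSCR. For the added comparisons it left 2 for vehicle against untreated in siPRMT1, 1169 for its difference from siSCR and 3 for the average over undifferentiated and day 4 cells. Of the 276 list tests 35 were called with an estimated correlation. The slope of the ATRA responses was 0.867 with arrays scaled to one SD. Leaving out 1 array gave 304 to 897 genes for the ATRA interaction and 29 to 36 for vehicle against untreated in siPRMT1, and every other count stayed within 1.5 times its value.

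Equal replicate numbers were not paired in the values: the correlation between same-numbered arrays had a median of 0.0122, from -0.502 to 0.606. With a replicate block the counts were 3756, 3653, 13155 and 13969 for the knockdown in the 4 states and 14257 for the average. For embryoid body formation, with the pairing of the same block, they were 5602, 8253 and 4746, for ATRA 4708, 2366 and 588, and for vehicle against untreated 12220.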

Other observations

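The tests in this part used lists and comparisons fixed before the values were seen, and the genes shown were chosen after. Other arginine methyltransferase genes moved in siPRMT1 as well. In undifferentiated cells Prmt8, the close relative of Prmt1 with a membrane anchor, was higher by 0.63 ± 0.080 and Prmt7 by 0.55 ± 0.043, while Prmt2 (-0.37 ± 0.067) and Prmt3 (-0.24 ± 0.067) were lower. At day 4 Prmt8 was lower (-0.40 ± 0.080), Prmt2 (0.45 ± 0.067) and Prmt3 (0.20 ± 0.067) were higher, and Prmt7 was not called (-0.026 ± 0.043). ATRA raised Prmt8 by 0.94 ± 0.080 in siSCR and 0.34 ± 0.080 in siPRMT1, and the difference was called (-0.60 ± 0.11). As a list, arginine methyltransferase genes were not called for the knockdown in undifferentiated cells (adjusted p = 0.678) or at day 4 (adjusted p = 0.941).

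Several imprinted genes behaved differently in the lines on aggregation. Igf2 rose by 0.96 ± 0.082 in siSCR and 1.84 ± 0.082 in siPRMT1, with a called difference of 0.88 ± 0.12, and Peg3 by 1.04 ± 0.096 and 1.78 ± 0.096. The maternally expressed RNA gene Meg3 rose in siSCR (0.84 ± 0.13) and fell in siPRMT1 (-0.35 ± 0.13), a difference of -1.19 ± 0.18, and ATRA lowered it in both lines (-0.65 ± 0.13 and -0.98 ± 0.13). At day 4 Dlk1 was lower in siPRMT1 (-0.98 ± 0.11) and Cdkn1c higher (0.88 ± 0.090). The list itself was not called for the aggregation difference (adjusted p = 0.605).

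Of the 23 lists, 7 were called in no planned comparison. For the knockdown at day 4 their counts were as follows. Primitive streak and mesendoderm genes were 3 higher, 0 lower and 13 not called of 16 measured (3 and 0 adjusted over the list alone), with Lhx1 at 1.04 ± 0.099, and mesoderm and blood-endothelial genes 6 higher, 2 lower and 14 not called of 22 measured (6 and 2 adjusted over the list alone), with the endothelial genes Cdh5 (0.75 ± 0.11) and Tek (0.62 ± 0.086) higher and Pecam1 (-0.72 ± 0.067) lower. Neural genes were 3 higher, 1 lower and 19 not called of 23 measured (3 and 1 adjusted over the list alone), and trophectoderm genes 3 higher, 2 lower and 11 not called of 16 measured (4 and 2 adjusted over the list alone), with the placental gene Plac1 at 1.11 ± 0.12. Wnt feedback genes were 4 higher, 1 lower and 7 not called of 12 measured (4 and 1 adjusted over the list alone), where Axin2 (0.46 ± 0.11), Notum (0.56 ± 0.12) and Dkk1 (0.66 ± 0.086) were higher. TGF-beta and BMP feedback genes were 2 higher, 4 lower and 9 not called of 15 measured (3 and 5 adjusted over the list alone), and p53 targets 5 higher, 2 lower and 12 not called of 19 measured (6 and 2 adjusted over the list alone). The adjusted p of these 7 tests by camera were 0.23, 0.243, 0.724, 0.665, 0.21, 0.805 and 0.427. With ATRA the neural gene Pax6 rose by 0.45 ± 0.099 in siSCR and 0.99 ± 0.099 in siPRMT1, and the Nodal antagonist gene Lefty1 by 1.26 ± 0.073 and 1.14 ± 0.073.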
